A study of Oryza sativa with 32 samples.

How the data were processed

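RNA from 32 rice panicle samples was measured, 4 at each of 8 times over a day in untreated field plants. Groups and replicate numbers were taken from the sample labels, and the hours after dawn from the same labels, which step by 3.5 h where the series description speaks of about 3 h. Dusk has no hour there and was set at 12 h after dawn in the rhythm model alone. Per the labels' protocols, tissue was ground and freeze-dried, total RNA was extracted with a silica column kit and a DNase step, poly(A) RNA was isolated on oligo(dT) beads, and libraries were made with a kit that keeps the strand. Per the submitters' processing notes, TopHat2 (version 2), HTSeq (version 0.6.0) and the rice genome build IRGSP-1.0 were used. The strand setting of the counting and the annotation release are not given in the sources used here. The samples are of an indica rice, and that build is of a japonica rice, so reads of diverged or absent genes can be missed, and whether this differs by time was not tested.

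The authors deposited a table of whole-number counts per gene and a table of CPM. The deposited CPM equalled the count divided by the library's total, in CPM units, so it holds no further scaling, and it served for a single alternative test. The count table has 37829 gene identifiers, of which 3564 were at 0 in all libraries, and each library had counts for 27084 to 31134 genes. Totals ran from 10.8 to 43.9 M counts (M for mega) per library (a ratio of 4.08), and the 10 most counted genes held 2.37 to 4.51% of a library. A count of 3, taken here as the floor, stands for between 3 counts in 10.8 M and 3 in 43.9 M, and low values carry counting error beyond the spread shown. Reads that map to near-identical copies, such as the LHCB1 genes, can be split or lost in counting, so values of such genes are uncertain.

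The files give identifiers without names, and the reference table used here (assembly ASM3414082v1) pairs 1 of its genes with an identifier of this kind. Symbols were therefore attached to identifiers by the gene lists, which were written from general knowledge of rice genes before the data were examined. Of 225 pairs in 19 lists, 141 symbols stood in the reference table on the chromosome and in the order that their identifier gives, 8 stood elsewhere and were dropped, and 76 were not in the table, which leaves 217 pairs in use. Of the genes named here, the pairing of PRR59, ELF3-2, FKF1, ZTL1, ZTL2, ELF4a, LHCA5, LHCB3, PRK, GAPB, SBPase, CRD1, AGPL3, GBSSII, SSIIIb, SSIVb, GWD1, BAM2, INV3, NIA2, NIR1, NADH-GOGAT2, HSP90-1, CATC, JAR2, MADS63, EXPB13, RISBZ1 and EEF1A was not checked by the table. No gene descriptions were used, so list members to be added by description, and a list of ribosomal proteins, were not analysed here. The lists are core clock, photoperiod and flowering, light harvesting, carbon fixation (Calvin cycle), chlorophyll synthesis, starch synthesis, starch breakdown, sugar metabolism, nitrogen assimilation, heat shock, redox, cold and dehydration, jasmonate, tapetum, mature pollen, endosperm storage, cell division, floral organ identity and reference genes.

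Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest at their default settings) in R 4.3.3, with TMM factors, the filterByExpr filter (25766 genes left) and Benjamini-Hochberg adjustment at 0.05. All 32 libraries entered each fit, with 1 mean per time in all but the rhythm fit. Changes over time were tested over the 8 means together. A 24 h rhythm was tested with a cosine and a sine term of 24 h, from which peak time and amplitude (peak against mean, log2) were taken. That fit holds no mean per time, so departures from a single wave enter its spread. Contrasts were dusk against dawn, the mean of 14, 17.5 and 21 h against the mean of 3.5, 7 and 10.5 h, and each time against the one before. For lists, the share of genes that changed over time was compared with that of other genes by Fisher's exact test (two-sided). This test counts genes as independent, although genes of a list can move together, so its p describes the list alone. Contrasts were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. Levels in the text are CPM with TMM factors, and list means are means of log2 CPM with a prior count of 2. Relations between list means were computed over the 32 libraries, each centred on the mean of its time, with 100000 permutations.

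Genes were named by a rule fixed before the data were examined: every core clock gene; up to 3 genes of each other list with the lowest adjusted p over time; the 10 genes with the largest rhythm amplitude; for dusk against dawn and night against day, the 8 largest rises and 8 largest falls without overlap of libraries, plus up to 3 genes of each list called by camera; and the 3 largest rises and falls of each interval. Of the list genes that this rule takes, 1 is left out of the text and of the values by gene. Genes taken by size had a mean of at least 10 CPM. Of those outside the lists, 2 that rose and 2 that fell at night are given, by identifier, and the others are not named in the text. Genes named in other ways are marked in the text as chosen after their values were seen.

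Alternatives fixed before the data were examined were a replicate block, DESeq2 size factors, no scaling beyond the library total, no filter beyond 1 count, a filter of at least 1 CPM in at least 4 libraries, robust empirical Bayes, a 2-fold minimum, DESeq2 1.42.0, limma-trend on log2 of the deposited CPM plus 1, the compared groups alone, other hours for dusk (11 h, 13 h, or dusk left out), a 12 h term, contrasts of the time means, and each of the 32 libraries left out in turn. Chosen after seeing the data were the version 4 test of edgeR, the mature pollen mean as a covariate, leaving out the 3 libraries with the lowest median correlation to their time, identifiers ending in 00 alone, and 10.5 h against 14 h.

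The steps were tested on simulated data drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold among 25766. Each gene was given the spread usual at its level, so genes noisier than that are not covered. No genes of low level were changed, so the shares do not describe them. For the 8 times the change was placed at dusk alone. Of the 4-fold genes, 84% were recovered for dusk against dawn, 99% for night against day, 96% for the rhythm and 88% over the 8 times; of the 2-fold genes, 20%, 80%, 51% and 13%. For the intervals, 80 to 88% of 4-fold and 14 to 30% of 2-fold changes were recovered. Few genes were changed in the simulation, which makes the adjusted threshold stricter than where many genes change. In the real data 2966 genes were called from dawn to 3.5 h, of which 957 differed by at least 2-fold. The recovered shares are therefore not those of the real intervals. Wrong calls were 7.14% of the calls for dusk against dawn, 3.24% for night against day, 2.65% for the rhythm and 5.61% over the 8 times. For the intervals they were 2.73 to 8.40%, with 8.40% from 10.5 h to dusk and 7.34% from dusk to 14 h. Simulated genes varied independently of each other, so these shares do not cover differences between samples that many genes have in common. Replicates of a time correlated at 0.851 to 0.984 (median 0.945), and no pair of libraries of a time agreed within sampling noise (lowest chi-square per degree of freedom 10.7). This does not tell separate samples from repeat libraries of a sample, and all were counted as separate samples. No column of the tables was left without a sample.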

Results

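The transcripts of rice panicles were sequenced at 8 times over a day. The plants were Oryza sativa IR64, an indica rice grown in a field in the Philippines, and the panicles (the flowering heads) were taken when 50% of flowering was reached, without treatment. Sampling began at dawn and went on at 3.5, 7 and 10.5 h after dawn, at dusk, and at 14, 17.5 and 21 h after dawn, with 4 libraries at each time and 32 in all. The labels give no hour for dusk. The hours used here are those of the labels, while the series description speaks of steps of about 3 h, so peak times and interval lengths rest on the labels. Each library was a poly(A)-selected, strand-marking library from total RNA. The labels do not say whether the 4 libraries of a time came from separate plants or plots, so the p-values measure the spread between these samples, which may be technical. Totals ran from 10.8 to 43.9 M counts (M for mega) per library with a median of 16.8 M. By time, they averaged 17.6 ± 7.03 M at dawn, 19.3 ± 7.97 M at 3.5 h, 19.5 ± 4.19 M at 7 h and 17.904 ± 4.52 M at 10.5 h (SD, n = 4 each). They averaged 18.9 ± 3.88 M at dusk, 21.8 ± 15.0 M at 14 h, 17.3 ± 8.58 M at 17.5 h and 14.5 ± 2.85 M at 21 h. Levels are TMM-scaled CPM as mean ± SD of 4 libraries. Log2 differences carry a standard error computed back from the test, as the difference divided by the square root of its F value.

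The first question was which transcripts differ over the day. Clock genes had a median range of 4.01 on the log2 scale between their highest and lowest time, second among the 19 gene lists to the light-harvesting genes with 5.79. LHY (OS08G0157600), a MYB factor of the morning loop of the plant clock, stood at 3827 ± 1319 CPM at dawn and at 21.7 ± 13.0 CPM at dusk, a 176-fold range. The pseudo-response regulators repress LHY-type genes in plants. Their highest means fell between 3.5 and 10.5 h: PRR73 (OS03G0284100) at 3.5 h (548 ± 61.3 CPM), PRR37 (OS07G0695100) and PRR95 (OS09G0532400) at 7 h (173 ± 31.2 and 317 ± 65.9 CPM) and PRR1 (OS02G0618200) at 10.5 h (144 ± 4.19 CPM). PRR73 still stood at 532 ± 36.0 CPM at 7 h, and these 2 times did not differ in the test (adjusted p = 0.925). GI (OS01G0182600), a clock and flowering-time protein, reached 1709 ± 49.6 CPM at 10.5 h and stood at 37.9 ± 3.22 CPM at 21 h. The F-box gene FKF1 (OS11G0547000) and the evening-complex gene LUX (OS01G0971800) were also highest at 10.5 h, with 165 ± 10.5 and 155 ± 23.4 CPM, against 3.20 ± 1.23 CPM at 21 h and 1.15 ± 0.512 CPM at 3.5 h. Other clock members moved less. PRR59 (OS11G0157600) changed 2.19-fold between 10.5 and 17.5 h. ELF4a (OS11G0621500) ranged from 11.4 ± 0.586 to 19.7 ± 2.39 CPM and ELF3-1 (OS06G0142600) from 36.8 ± 4.33 to 61.1 ± 12.1 CPM. ELF3-2 (OS01G0566100) went from 6.21 ± 1.81 to 14.7 ± 3.28 CPM and ZTL2 (OS02G0150800) from 84.7 ± 14.3 to 121 ± 13.2 CPM. ZTL1 (OS06G0694000), a paralogue of ZTL2, stood between 148 ± 12.5 and 177 ± 12.5 CPM and did not pass the test (adjusted p = 0.0547). In all, 13 of the 14 clock genes passed (14 adjusted over the list alone). This was a larger share than among other genes (Fisher's exact test, two-sided, adjusted p = 7.1e-04). Over all genes, 10852 of 25766 tested (42.1%) differed between the 8 times in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 5901 had a range of at least 2-fold between time means. This range takes the highest and lowest of 8 means, so it runs high. In the simulated data a true 2-fold change gave a median range of 1.35 on the log2 scale. ELF3-2 missed the threshold without dawn replicate 2 or without replicate 1 of 10.5 h (highest adjusted p 0.0668). ZTL2 missed it without scaling beyond the library total, and without dusk replicate 2, dusk replicate 3, or replicate 2 or 4 of 21 h (highest adjusted p 0.0632). ZTL1 passed in 19 of 45 alternative fits.

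**Figure D1:**
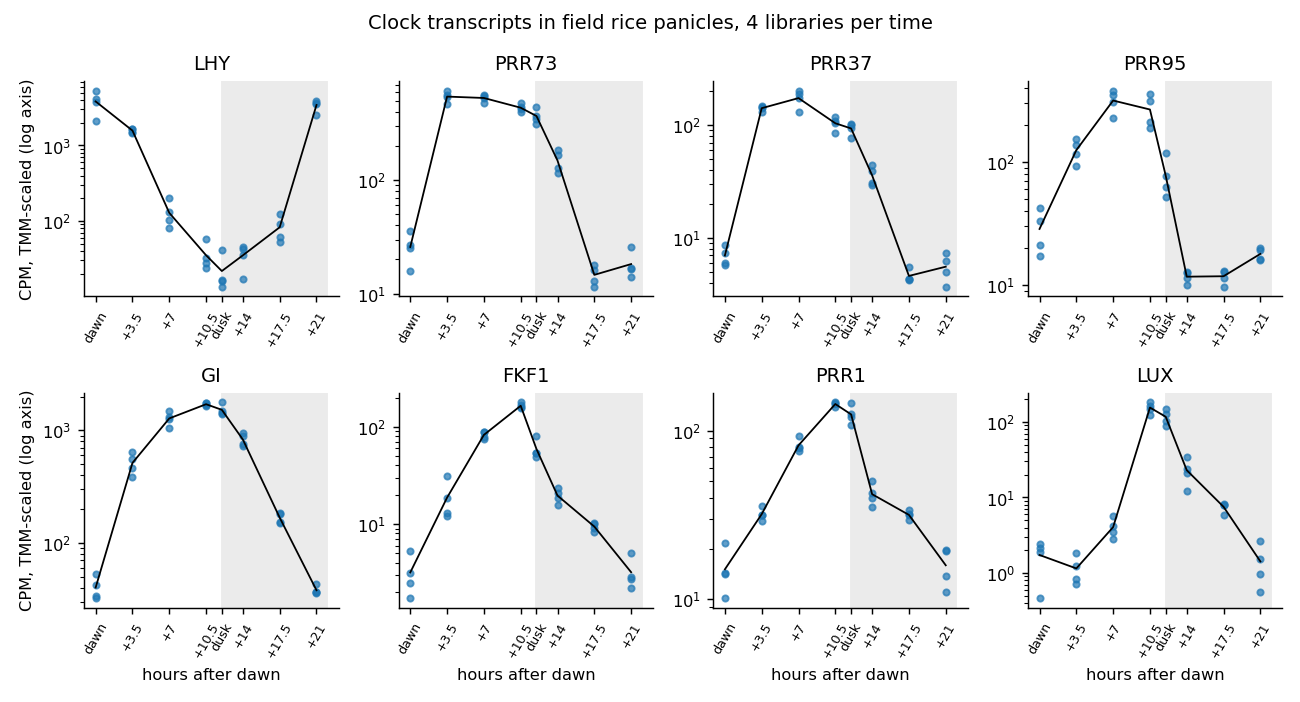
TMM-scaled CPM (log axis) of 8 clock transcripts against hours after dawn, as points per library with a line through the time means; shading starts at dusk, drawn at 12 h. LHY was highest at dawn and PRR73, PRR37, PRR95, GI, FKF1, PRR1 and LUX were highest between 3.5 and 10.5 h.

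All light-harvesting and chlorophyll synthesis genes changed over the day, and carbon fixation, starch and sugar genes in part. The light-harvesting genes encode the chlorophyll a/b-binding antenna proteins. All 13 passed the test (13 adjusted over the list alone, Fisher's exact test adjusted p = 2.5e-04). LHCB1-c (OS09G0346500) went from 4476 ± 1448 CPM at 3.5 h to 41.1 ± 7.95 CPM at 17.5 h. At the same times LHCB2 (OS03G0592500) went from 2546 ± 910.0 to 23.4 ± 3.60 CPM and LHCB3 (OS07G0562700) from 1312 ± 479 to 18.7 ± 1.82 CPM. All 11 chlorophyll synthesis genes also passed (11 adjusted over the list alone, adjusted p = 7.0e-04). CAO1 (OS10G0567400) and CRD1 (OS01G0279100), which make chlorophyll b and the fifth ring of chlorophyll, were highest at dawn with 513 ± 236 and 1087 ± 652 CPM. CHLH (OS03G0323200), a subunit of magnesium chelatase, stood at 705 ± 169 CPM at 3.5 h and 46.2 ± 11.5 CPM at 14 h. Of the carbon fixation genes 6 of 10 passed (6 adjusted over the list alone, adjusted p = 0.460 for the share). RCA (OS11G0707000), the rubisco activase, went from 6271 ± 3282 CPM at dawn to 187 ± 58.9 CPM at 10.5 h. SBPase (OS04G0234600) and PRK (OS02G0698000), both of the Calvin cycle, went from 875 ± 383 and 793 ± 399.7 to 244 ± 47.3 and 269 ± 43.9 CPM at these times. Of the starch synthesis genes 11 of 23 passed (12 adjusted over the list alone, adjusted p = 0.740 for the share). GBSSII (OS07G0412100), a granule-bound starch synthase, stood at 468 ± 67.9 CPM at dawn and 38.0 ± 21.0 CPM at 14 h. SSIIIb (OS04G0624600) and SSIIb (OS02G0744700) were highest at 3.5 h (362 ± 30.9 and 82.4 ± 6.87 CPM) and lowest at 14 h (56.3 ± 11.1 and 20.8 ± 3.29 CPM). Of the starch breakdown genes 3 of 6 passed (3 adjusted over the list alone, adjusted p = 0.740). BAM2 (OS10G0565200), a beta-amylase, reached 99.2 ± 23.2 CPM at 21 h against 3.51 ± 2.90 CPM at 7 h. GWD1 (OS06G0498400), a glucan, water dikinase, reached 739 ± 52.8 CPM at 10.5 h against 335 ± 35.7 CPM at dawn. At the same times the amylase AMY3D (OS08G0473900) stood at 3.83 ± 4.63 against 0.334 ± 0.228 CPM. Of the sugar genes 9 of 17 passed (10 adjusted over the list alone, adjusted p = 0.586). The sucrose transporter SUT2 (OS12G0641400) was highest at 21 h (117 ± 15.7 CPM), the cell wall invertase CIN1 (OS02G0534400) at 7 h (346 ± 71.9 CPM) and the sucrose synthase SUS4 (OS03G0340500) at 10.5 h (249 ± 87.8 CPM). In the same order, they were lowest at dusk (50.5 ± 7.01 CPM), 14 h (153 ± 24.5 CPM) and 21 h (89.6 ± 15.6 CPM).

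The heat shock and nitrogen lists held a larger share of changed genes than other genes did, and for the redox and cold lists the share test missed the threshold. All 6 heat shock genes passed (6 adjusted over the list alone, adjusted p = 0.0177 for the share), and the 3 named here had their highest means at 3.5 h. The factors HSFB2c (OS09G0526600) and HSFA2d (OS03G0161900) reached 73.5 ± 3.75 and 77.6 ± 16.4 CPM against 2.26 ± 0.363 CPM at dusk and 8.66 ± 2.14 CPM at 14 h. The chaperone HSP101 (OS05G0519700) reached 65.3 ± 11.9 against 14.4 ± 3.84 CPM at 14 h. Of the nitrogen genes 8 of 9 passed (8 adjusted over the list alone, adjusted p = 0.0177). NIA1 (OS08G0468100), a nitrate reductase, stood at 7.89 ± 2.95 CPM at 21 h and 0.291 ± 0.174 CPM at 14 h. NADH-GOGAT2 (OS05G0555600), a glutamate synthase, and the nitrite reductase NIR1 (OS01G0357100) were highest at 7 h (52.2 ± 20.6 and 14.8 ± 1.42 CPM). The catalase CATA (OS02G0115700) reached 5014 ± 713 CPM at 10.5 h from 257 ± 49.2 CPM at dawn. The ascorbate peroxidase APX2 (OS07G0694700) was highest at 3.5 h (836 ± 113 CPM) and so was CATC (OS03G0131200) (476 ± 124 CPM). In all, 6 of 10 redox genes passed (6 adjusted over the list alone, adjusted p = 0.460). Of 7 cold and dehydration genes 5 passed (6 adjusted over the list alone, adjusted p = 0.242), and the 3 named here stood at low levels. The dehydrins RAB16D (OS11G0453900) and RAB16A (OS11G0454300) reached 1.29 ± 0.791 CPM at dawn and 5.37 ± 2.92 CPM at 3.5 h, and DREB1B (OS09G0522000) 1.71 ± 2.17 CPM at 17.5 h. RAB16A missed the threshold without replicate 3 of 3.5 h (adjusted p 0.0541), and DREB1B without replicate 1 of 17.5 h (highest adjusted p 0.317). DREB1B also missed it with the replicate block, with limma-trend and without the 3 libraries with the lowest correlation to their time.

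The other lists describe flowering, organs and cell types of the panicle. Of the photoperiod and flowering genes 9 of 14 passed (10 adjusted over the list alone, adjusted p = 0.229 for the share). Hd3a (OS06G0157700), a rice florigen, stood at 19.3 ± 7.97 CPM at 3.5 h and 1.80 ± 0.295 CPM at dusk. MADS18 (OS07G0605200) stood at 112 ± 31.2 CPM at dawn and 55.4 ± 3.12 CPM at 10.5 h, and MADS14 (OS03G0752800) at 76.5 ± 6.09 CPM at 21 h and 35.2 ± 5.81 CPM at dusk. Jasmonate genes changed in 10 of 16 cases (10 adjusted over the list alone, adjusted p = 0.242). The synthesis gene AOC (OS03G0438100) and the repressor gene TIFY11C (OS03G0180900) were highest at 3.5 h (158 ± 43.1 and 131 ± 90.4 CPM), and TIFY10C (OS09G0439200) at 10.5 h (77.3 ± 15.9 CPM). None of the 12 cell division genes passed in edgeR (0 adjusted over the list alone), a smaller share than among other genes (Fisher's exact test adjusted p = 0.0093). That test counts the genes as independent, while their estimated correlation was 0.92 (dusk against dawn). Their mean also went against the mature pollen list within times (r = -0.64). MCM5 (OS02G0797400) had the lowest adjusted p (0.143), with 54.8 ± 8.17 CPM at 17.5 h and 26.5 ± 11.3 CPM at 10.5 h. Of the floral organ identity genes 1 of 13 passed (0 adjusted over the list alone, adjusted p = 0.0291). MADS5 (OS06G0162800) ranged from 55.3 ± 7.79 to 74.6 ± 14.2 CPM and missed the threshold in 16 of 45 alternative fits. None of the 6 mature pollen genes passed in edgeR (0 adjusted over the list alone, adjusted p = 0.103). MADS63 (OS06G0223300), a pollen MADS-box gene, stood at 7.63 ± 11.8 CPM at 10.5 h and 0.563 ± 0.901 CPM at 17.5 h (adjusted p = 0.108), and it passed in 2 of 45 alternative fits. Tapetum genes, active in the cell layer that feeds pollen, passed in 5 of 10 cases (6 adjusted over the list alone, adjusted p = 0.751). CYP703A3 (OS08G0131100) stood at 2.76 ± 0.392 CPM at dusk and 0.454 ± 0.122 CPM at 3.5 h, and UDT1 (OS07G0549600) at 4.43 ± 1.49 CPM at dawn and 2.04 ± 0.403 CPM at 3.5 h. EAT1 (OS04G0599300) stood at 2.71 ± 3.98 CPM at 10.5 h and missed the threshold with limma-trend or without replicate 1 of 10.5 h (highest adjusted p 0.0915). Of 3 endosperm storage genes 2 passed (2 adjusted over the list alone, adjusted p = 0.685). RISBZ1 (OS07G0182000), a storage protein factor, stood at 4.05 ± 1.91 CPM at 3.5 h and 0.594 ± 0.132 CPM at 10.5 h, and GluA2 (OS10G0400200) at 10.2 ± 1.30 CPM at dusk and 3.59 ± 0.705 CPM at 3.5 h. Of 4 genes often used as constant references 3 passed (3 adjusted over the list alone, adjusted p = 0.460). GAPDH (OS08G0126300) ranged from 1182 ± 179 to 2237 ± 185 CPM and EEF1A (OS03G0177400) from 364 ± 31.9 to 489 ± 71.2 CPM. EEF1A missed the threshold in 15 of 45 alternative fits.

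The mature pollen list differed between libraries of one time more than between times. It went with the largest axis of variation in the data, the first principal component of the 5000 most variable genes. This component held 39.5% of their variance, and 27.1% of the component lay between times. Without centring on times, it had r = 0.93 with the mature pollen list, 0.85 with tapetum and -0.74 with cell division. It had r = 0.85 with starch breakdown as well, 0.69 with jasmonate and 0.64 with reference genes. The mean log2 CPM of the mature pollen list had a standard deviation of 1.22 within a time and a 21.2-fold range over the 32 libraries. With each library centred on its time, it went with the tapetum list (r = 0.88, rho = 0.82, and r = 0.83 without the 2 farthest libraries). Permutation p was 2e-05 for r and 3e-05 for rho, with adjusted p of 6e-05 and 9e-05. It also went with the starch breakdown list (r = 0.79, rho = 0.78, and r = 0.78 without the 2 farthest). Permutation p was 1e-05, the smallest that 100000 permutations can give, and 2e-05, with adjusted p of 6e-05 and 9e-05. It went weakly with the jasmonate list (r = 0.57, rho = 0.51, r = 0.53 without the 2 farthest, permutation p = 0.0022 and 0.0074, adjusted p = 0.0033 and 0.011). It went against the cell division list (r = -0.64, rho = -0.64, r = -0.66 without the 2 farthest, permutation p = 0.0013 and 0.00071, adjusted p = 0.0026 and 0.0014). It showed no relation past the threshold with the floral organ identity list (r = 0.26, rho = 0.31, r = 0.095 without the 2 farthest, permutation p = 0.268 and 0.139, adjusted p = 0.322 and 0.167). The same held for the library total (r = 0.13, rho = 0.12, r = 0.17 without the 2 farthest, permutation p = 0.532 and 0.559, adjusted p = 0.532 and 0.559). These were 6 relations, adjusted together, and the labels give no sequencing batch within which to repeat them.

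**Figure D2:**
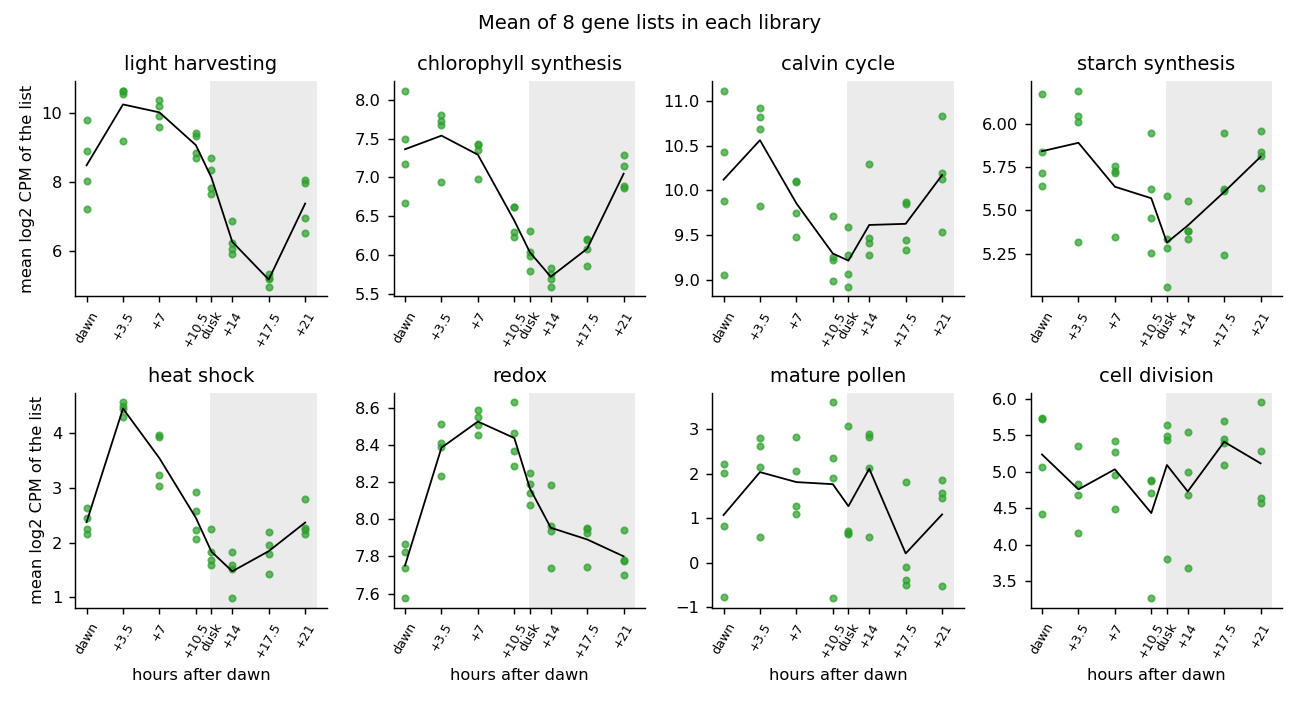
Mean log2 CPM of 8 gene lists (vertical axes) against hours after dawn, as points per library with a line through the time means; shading starts at dusk, drawn at 12 h. Light harvesting, chlorophyll synthesis, heat shock and redox means were lower at 14 and 17.5 h than at 3.5 and 7 h, while mature pollen genes varied by 21.2-fold between libraries with overlap of the times.

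**Figure D3:**
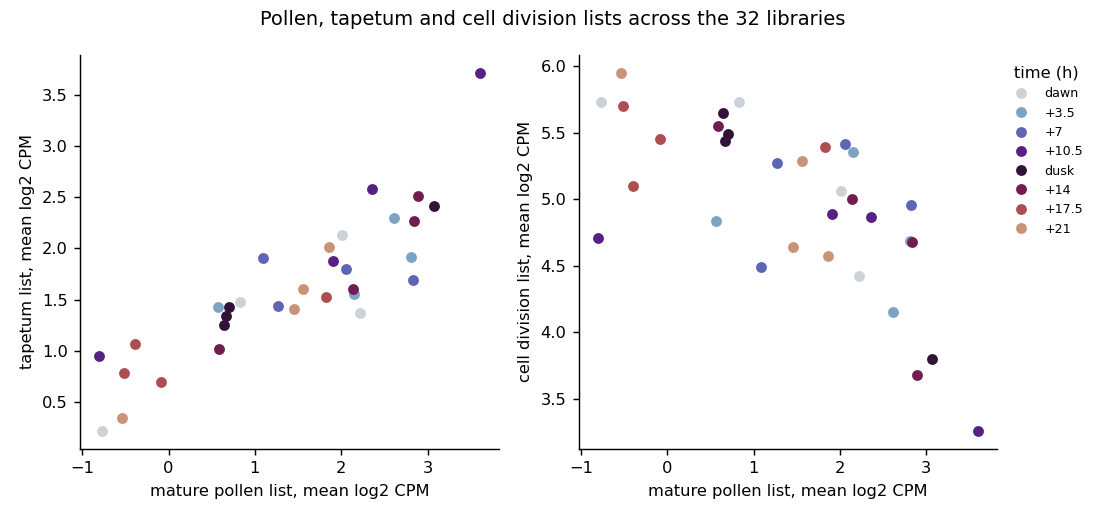
Mean log2 CPM of the tapetum list (left) and of the cell division list (right) against that of the mature pollen list in the 32 libraries, coloured by time in hours after dawn. Libraries of one time are spread along both relations, which had r = 0.88 and r = -0.64 with each library centred on its time.

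The second question was when over the day each transcript peaks. LHY peaked at dawn, with a fitted peak at 0.014 ± 0.21 h and an amplitude of 3.87 on the log2 scale. Peaks are from the edgeR fit, and their standard errors are from a least-squares fit of the same wave to log2 CPM. PRR95 followed at 6.96 ± 0.27 h, PRR37 at 7.67 ± 0.19 h and PRR73 at 7.75 ± 0.21 h. These 3 stand in another order by their highest means, where PRR73 was first (3.5 h), so the single wave does not settle their order. Later came FKF1 at 9.42 ± 0.22 h, GI at 9.58 ± 0.17 h, PRR1 at 10.1 ± 0.26 h and LUX at 11.9 ± 0.38 h. Among the lists, the chlorophyll synthesis genes had a mean peak at 2.40 h, the heat shock genes at 3.73 h and the light-harvesting genes at 4.90 h. All of their 11, 6 and 13 members were called (the same numbers adjusted over the list alone). A single 24 h wave was called for 13 of 14 clock genes (13 adjusted over the list alone), with the exception of PRR59 (adjusted p = 0.121). Over all genes, 12201 of 25766 (47.4%) had such a wave in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The median amplitude was 0.41 on the log2 scale, and 4930 genes differed at least 2-fold between peak and trough. Fitted peaks fell most often between 9 and 12 h after dawn (2377 genes) and least often between 15 and 18 h (1032) and between 3 and 6 h (1037). There were 1629 between 0 and 3 h, 1391 between 6 and 9 h, 1477 between 12 and 15 h, 1514 between 18 and 21 h and 1744 between 21 and 24 h. A single cycle was sampled, so a 24 h wave cannot be told from a change that happened once, and dusk was placed at 12 h. With dusk at 13 h the peaks of PRR37 and PRR73 moved by 0.24 and 0.23 h, over their standard errors.

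The third comparison set the light transitions named in the labels against each other. At dusk, 9 of 14 clock genes stood above their dawn level. LUX rose 66.9-fold from 1.73 ± 0.875 to 117 ± 27.0 CPM and GI 38.0-fold from 40.1 ± 9.32 to 1523 ± 168 CPM. PRR73 and PRR37 rose 14.3-fold and 13.4-fold, while LHY fell by 7.46 on the log2 scale (standard error 0.48). Some starch synthesis genes were lower at dusk, with GBSSII at 45.5 ± 12.9 CPM (10.3-fold lower than at dawn) and SSIIIb at 64.5 ± 9.00 CPM (4.15-fold lower). AGPS2 (OS08G0345800), a subunit of ADP-glucose pyrophosphorylase, stood at 114 ± 10.1 against 299.5 ± 90.4 CPM. So were some chlorophyll synthesis genes, with CAO1 11.9-fold, CRD1 10.2-fold and CHLH 6.25-fold lower. Among carbon fixation genes RCA was 28.2-fold lower (222 ± 38.5 CPM at dusk), SBPase 3.42-fold and PRK 2.86-fold lower. Heat shock factors HSFA2d, HSFB2c and HSFA2c (OS10G0419300) were 4.13-fold, 4.10-fold and 1.84-fold lower at dusk. Their relative HSFA2a (OS03G0745000), named after its value was seen, rose (log2 3.60 ± 0.92). The clock list was higher at dusk as a set, with 9 members up and 3 down (9 and 4 adjusted over the list alone). Its camera test gave adjusted p = 1.1e-15, and 0.0054 with an estimated correlation. Lower at dusk was starch synthesis with 10 of 23 down (1 up and 10 down adjusted over the list alone, camera adjusted p = 4.7e-05). So were chlorophyll synthesis with 6 of 11 down (1 up and 6 down adjusted over the list alone, adjusted p = 1.1e-06) and carbon fixation with 4 of 10 down (4 adjusted over the list alone, adjusted p = 0.0034). Heat shock genes were lower with 4 down and 1 up of 6 (4 and 1 adjusted over the list alone, adjusted p = 0.0280). With an estimated correlation these 4 calls were lost, with adjusted p = 0.131, 0.278, 0.794 and 0.340 in the same order. Of 10 redox genes 3 rose, CATA among them (log2 3.78 ± 0.21), and 1 fell (4 and 2 adjusted over the list alone). This list missed the camera threshold (adjusted p = 0.0546), and with the replicate block it passed (camera adjusted p = 0.047). Over all genes 5694 differed in the edgeR quasi-likelihood test. At dusk 2953 were higher and 2741 lower, and 2669 differed by at least 2-fold. Without scaling beyond the library total the calls were 3342 higher and 1885 lower. The median of all genes then lay 0.16 higher on the log2 scale, so directions are relative to the scaled median. With the 8 compared libraries alone in the fit 3175 genes were called. Mature pollen genes differed within both times, from -0.77 to 2.22 (mean log2 CPM) at dawn and from 0.64 to 3.07 at dusk.

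The fourth comparison set the 3 times inside the night (14, 17.5 and 21 h) against the 3 times inside the day (3.5, 7 and 10.5 h), with 12 libraries each. Antenna genes were lower at night, LHCB1-c 40.6-fold, LHCB2 24.4-fold, LHCB1-a (OS01G0600900) 22.3-fold and LHCB3 20.3-fold. In all 12 of the 13 light-harvesting genes fell (12 adjusted over the list alone). The exception was LHCA5 (OS02G0764500) (log2 0.20 ± 0.15, adjusted p = 0.361, named after its value was seen). Some clock genes fell as well, PRR73 14.7-fold, PRR37 14.0-fold and GI 5.97-fold. Of the clock genes 7 were down and ELF3-1 was up (log2 0.34 ± 0.09, 8 down and 1 up adjusted over the list alone). All 6 heat shock genes were lower at night (6 adjusted over the list alone), among them HSP90-1 (OS04G0107900) 7.95-fold, HSFB2c 4.45-fold and HSFA2d 2.96-fold. HSP90-1 stood near the floor at 14 h (0.275 ± 0.224 CPM, against 8.98 ± 5.31 CPM at 3.5 h), so its fold is uncertain. Its log2 difference ran from -3.29 to -1.52 over the alternatives. Of 10 redox genes 6 were lower (6 adjusted over the list alone), among them CATA 5.14-fold, APX2 2.37-fold and the superoxide dismutase SOD-Cu1 (OS03G0351500) 1.47-fold. In chlorophyll synthesis 8 genes fell and 2 rose (9 and 2 adjusted over the list alone). CHLH was 3.40-fold, PORB (OS10G0496900) 2.95-fold and DVR (OS03G0351200) 2.12-fold lower. These 5 lists were lower as sets. Camera gave adjusted p = 1.3e-44 for light harvesting, 1.1e-32 for the clock, 4.3e-07 for heat shock, 2.9e-06 for redox and 3.3e-05 for chlorophyll synthesis. With an estimated correlation the adjusted p was 0.0017, 2.9e-05, 0.007 and 0.01 for the first 4. The call for chlorophyll synthesis was lost (adjusted p = 0.271 with an estimated correlation), and its mean was higher in every 21 h library than in any 10.5 h library. Heat shock means overlapped between these 2 times. Among genes that the lists do not name, OS04G0583900 was 40.2-fold higher at night (91.5 ± 46.6 against 2.55 ± 1.77 CPM, n = 12) and OS01G0292700 8.45-fold higher. OS09G0287000 was 31.8-fold lower (0.896 ± 0.865 against 26.2 ± 16.93 CPM) and OS01G0837600 26.9-fold lower. Over all genes 6792 differed in the edgeR quasi-likelihood test, 3172 higher and 3620 lower at night. Of the 1168 that differed by at least 2-fold 261 were higher and 907 lower. Without scaling beyond the library total the calls were 4849 higher and 2354 lower, with the median of all genes 0.096 higher on the log2 scale.

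Intervals between consecutive times showed when in the day the changes fell. From dawn to 3.5 h PRR73 rose 21.2-fold, PRR37, PRR95, GI, FKF1 and PRR1 rose, and LHY and PRR59 fell. In the same interval all 6 heat shock genes rose, as did 8 of 13 light-harvesting genes, 5 of 16 jasmonate genes and 3 of 10 redox genes. The jasmonate list goes with the mature pollen list across libraries (r = 0.57), whose means ran from -0.77 to 2.22 at dawn and from 0.57 to 2.81 at 3.5 h (log2 CPM). In all 2966 genes were called (1409 up, 1557 down), and of those that differed by at least 2-fold 709 were up and 248 down. From 3.5 to 7 h 3 heat shock genes, 3 carbon fixation genes and 4 starch synthesis genes fell, among 2221 genes (1364 up, 857 down). From 7 to 10.5 h LUX rose 38.4-fold, while 6 of 23 starch synthesis genes fell and 1 rose. Of 11 chlorophyll synthesis genes 4 fell, CAO1 (log2 -2.16 ± 0.23) and CHLH (-1.60 ± 0.28) among them, in a set of 1069 genes (467 up, 602 down). Calls are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Without scaling beyond the library total the first interval gave 960 up and 2225 down and the second 1570 up and 593 down, with the median of all genes at -0.14 and 0.14. With DESeq2 size factors the second gave 1147 up and 1099 down. With the 8 compared libraries alone, 627 genes were called from dawn to 3.5 h (435 up, 192 down), so the balance of directions depends on these choices. In that interval 1970 were called without dawn replicate 2, and 1166 from 3.5 to 7 h without replicate 3 of 3.5 h.

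Around dusk few genes passed the test, and clock and antenna genes were among them. From 10.5 h to dusk PRR95 fell by 1.79 and FKF1 by 1.48 on the log2 scale, among 48 genes (9 up, 39 down). From dusk to 14 h 8 clock genes fell, PRR95 by 2.73, LUX by 2.35 and PRR1 by 1.57 on the log2 scale. In that interval 6 light-harvesting genes fell, LHCB1-c 8.98-fold, and RCA rose 3.06-fold, among 161 genes (9 up, 152 down). These intervals join dusk, which has no hour in the labels, so the length of each is not known. Together they span the 3.5 h from 10.5 to 14 h, so each is shorter than the other intervals. Their counts are therefore not on a par with those of the other intervals. The first count rests on single libraries and settings. It was 28, 15 and 24 without replicate 1, 3 or 4 of 10.5 h, and 244, 13, 21 and 24 without dusk replicate 1, 2, 3 or 4. The 244 were 147 up and 97 down, so the balance of directions turned without dusk replicate 1. It was 27 (11 up, 16 down, median of all genes 0.11) without scaling beyond the library total. It was 0 with the 8 compared libraries alone in edgeR (2589 at unadjusted p under 0.05). With all libraries in the fit it was 328 with DESeq2 and 28 with limma-trend. The second was 100 without dusk replicate 3, 82 and 95 without replicate 2 or 3 of 14 h, 48 with the 8 compared libraries alone and 327 with DESeq2. RCA had an adjusted p of 0.0544 with the 8 libraries alone. Dusk replicate 3 held 3.04% of its counts at identifiers whose number does not end in 00, against a median of 2.13% over the libraries. Dusk replicate 1 had a mature pollen mean of 3.07 (log2 CPM) against 0.64 to 0.70 in the other dusk libraries.

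Clock genes changed in both directions from 14 to 21 h. From 14 to 17.5 h PRR73 fell by 3.35, PRR37 by 2.96 and GI by 2.31 on the log2 scale. BAM2 rose 5.03-fold and 3 starch synthesis genes rose, GBSSII by 1.76, SSIIIb by 1.05 and SSIIb by 0.95, among 354 genes (222 up, 132 down). From 17.5 to 21 h LHY rose 41.6-fold. Also up were 12 of 13 light-harvesting genes, 5 of 23 starch synthesis genes and 4 of 11 chlorophyll synthesis genes. GI, LUX, FKF1, PRR1 and ELF4a fell, among 2208 genes (1299 up, 909 down) in the edgeR quasi-likelihood test. Without scaling beyond the library total the last interval gave 835 up and 1675 down, with the median of all genes at -0.24, so its direction over all genes depends on the scaling. The count from 14 to 17.5 h was 100 and 207 without replicate 1 or 3 of 14 h, and 156, 151 and 137 without replicate 1, 2 or 3 of 17.5 h. It was 111 with the 8 compared libraries alone and 1284 with DESeq2. With the mature pollen mean as a covariate, chosen after seeing the data, it was 236, of which 180 were among the 354. Mature pollen means ran from 0.58 to 2.89 at 14 h and from -0.51 to 1.82 at 17.5 h (log2 CPM). The count from 17.5 to 21 h was 1412 without replicate 1 of 17.5 h and 3385 without replicate 3 of 21 h.

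**Figure D4:**
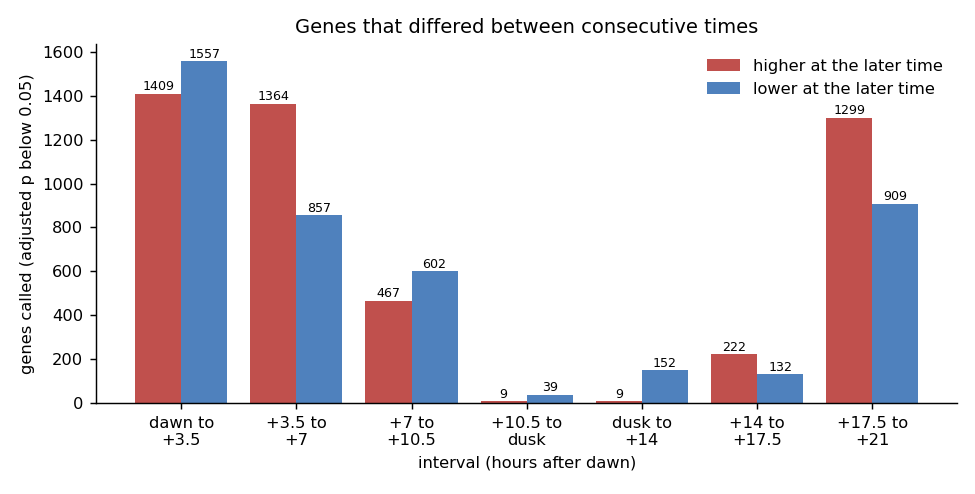
Number of genes called (vertical axis) as higher or lower at the later of 2 consecutive times (horizontal axis, hours after dawn), from the edgeR quasi-likelihood test at an adjusted p under 0.05. Bars for the intervals before and after dusk stand at 48 and 161 genes in all, against 2966 from dawn to 3.5 h and 2208 from 17.5 to 21 h. Both intervals that join dusk are shorter than the others.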

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

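In groups of 4 libraries, the highest or lowest library was set against the others by Dixon's test at the 95% level, for each named gene at its highest and lowest time, at dusk and dawn if it was named for that comparison, and for the library total at each time. Of 163 groups, 15 held such a library, while chance gives about 1 in 20. Values are CPM of the library that stood apart, and no explanation was tested for any of them.

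Dusk held 4 of them: LHY stood at 41.1 CPM in dusk replicate 1, CHLH at 151 and CRD1 at 118 in the same library, all above the others, and RCA at 165 CPM in dusk replicate 3, below them. At dawn HSFA2c stood low in replicate 4 with 16.3 CPM. At 3.5 h HSFB2c was low in replicate 2 (67.9 CPM) and CYP703A3 in replicate 4 (0.274 CPM). At 10.5 h MADS63 (25.2 CPM) and EAT1 (8.60 CPM) were high in replicate 1, the library with the highest mature pollen mean, and AMY3D was high in replicate 3 (10.8 CPM). At 17.5 h PRR37 was high in replicate 3 (5.55 CPM), DREB1B in replicate 1 (4.92 CPM) and MADS63 in replicate 2 (1.90 CPM). At 21 h replicate 4 was high for GI (42.7 CPM) and low for NIA1 (3.48 CPM).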

How the results depend on the processing

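Alternatives with the mature pollen covariate, the 3 libraries left out, identifiers ending in 00 alone and the version 4 test of edgeR were chosen after seeing the data. The 106 pairs of a named gene and a comparison gave 4818 values under the alternatives. Of these, 4745 kept their direction and side of the threshold, 52 lost the call and 21 gained it, while 91 pairs held under all alternatives run. Of the 45 pairs that have a direction, 0 changed it.

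With a 2-fold minimum, which by its construction counts fewer genes, the calls were 5901 over time, 4930 for the rhythm, 2669 for dusk against dawn and 1168 for night against day. The count over time uses the range between the highest and lowest mean, which runs high. For the intervals in order they were 957, 988, 573, 29, 102, 172 and 1035. With only the compared groups in the fit, which leaves fewer samples to estimate the spread, they were 3175 for dusk against dawn, 627 from dawn to 3.5 h, 48 from dusk to 14 h and 111 from 14 to 17.5 h. They were 0 from 10.5 h to dusk (edgeR, 2589 at unadjusted p under 0.05). With all libraries in the fit, DESeq2 gave 328 from 10.5 h to dusk, 327 from dusk to 14 h and 1284 from 14 to 17.5 h. From 10.5 h to dusk the count was also 27 without scaling beyond the library total, 28 with limma-trend, 106 with the mature pollen covariate and 27 without the 3 libraries with the lowest correlation to their time. Without these 3 it was 560 from 14 to 17.5 h and 4473 from 17.5 to 21 h. The cause was not tested for these. The 3 libraries were dawn replicate 4, dusk replicate 3 and replicate 3 of 21 h.

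Leaving out each of the 32 libraries in turn gave 9836 to 12084 genes over time, 11610 to 12704 for the rhythm, 4363 to 6764 for dusk against dawn and 6130 to 7178 for night against day. For the intervals it gave 1970 to 3587, 1166 to 2665, 762 to 1208, 13 to 244, 82 to 207, 100 to 512 and 1412 to 3385. Counts that moved by over 1.5 times were 1970 without dawn replicate 2 (dawn to 3.5 h) and 1166 without replicate 3 of 3.5 h (3.5 to 7 h). From 10.5 h to dusk they were 28, 15 and 24 without replicate 1, 3 or 4 of 10.5 h and 244, 13, 21 and 24 without dusk replicate 1, 2, 3 or 4. From dusk to 14 h they were 100 without dusk replicate 3, and 82 and 95 without replicate 2 or 3 of 14 h. From 14 to 17.5 h they were 100 and 207 without replicate 1 or 3 of 14 h, and 156, 151 and 137 without replicate 1, 2 or 3 of 17.5 h. From 17.5 to 21 h they were 1412 without replicate 1 of 17.5 h and 3385 without replicate 3 of 21 h.

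For the lists, adjusted p with an estimated correlation was 0.794 for carbon fixation, 0.278 for chlorophyll synthesis, 0.131 for starch synthesis and 0.340 for heat shock (dusk against dawn). It was 0.271 for chlorophyll synthesis (night against day). With fry, which does not compare a list with other genes, calls were added for redox (1.3e-04, dusk against dawn), nitrogen assimilation (8.2e-05), cold and dehydration (0.0092) and reference genes (4.0e-07, night against day). The median and the camera direction differed in sign for lists that were not called: carbon fixation, starch synthesis and starch breakdown (night against day) and sugar metabolism (dusk against dawn).

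Replicate numbers are shared by all times. Over the 5000 most variable genes, same-numbered libraries deviated from their time means with little correlation on average, and this was not tested. Their correlations averaged 0.061 (-0.81 to 0.78, with 55 of 112 pairs over 0.1), against -0.014 for different numbers, and 9 of 32 libraries correlated best with their own number. In list means, looked at after seeing the data, replicate 4 was lowest for light harvesting at 7 of 8 times, and for carbon fixation and chlorophyll synthesis at 6 of 8. With numbers shuffled within times, 502 of 10000 shuffles held a list as one-sided as the first (permutation test over all lists, p = 0.0503), so a factor shared by replicate 4 is not excluded. With the replicate block 11215 genes were called over time, 12398 for the rhythm, 5808 for dusk against dawn, 7201 for night against day and 76 from 10.5 h to dusk. Redox genes had an adjusted p of 0.047 for dusk against dawn, and over time DREB1B and MADS5 missed the threshold and ZTL1 passed it. With the block the other intervals stayed within 1.5 times and no other list changed its call.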

Other observations

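Lists that camera did not call still held members that moved in opposite directions between night and day (log2 differences with their standard error; genes chosen after their values were seen). In nitrogen assimilation, the nitrate reductases NIA1 (-1.12 ± 0.33) and NIA2 (-1.47 ± 0.33), NIR1 (-1.04 ± 0.15) and NADH-GOGAT2 (-2.42 ± 0.23) were lower over the 3 night times together. NIA1 had its highest mean of all 8 times at one of them, 21 h. FdGOGAT, the ferredoxin-dependent glutamate synthase, was higher (0.71 ± 0.08). Of these genes 4 of 9 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.224). In starch synthesis, SSIIb (-0.69 ± 0.10) and SSIIIb (-0.62 ± 0.08) were lower at night. The ADP-glucose pyrophosphorylase subunit AGPL3 (0.59 ± 0.09), SSIVb (0.43 ± 0.05) and the isoamylase ISA1 (0.84 ± 0.12) were higher, with 3 of 23 down and 3 up (the same adjusted over the list alone, camera adjusted p = 0.988). In carbon fixation, RCA (0.73 ± 0.17), SBPase (0.44 ± 0.16) and cpFBPase (0.66 ± 0.13) were higher at night and GAPB lower (-0.77 ± 0.15). This list had 3 up and 1 down of 10 (the same adjusted over the list alone, camera adjusted p = 0.988). The florigen Hd3a (-0.80 ± 0.28) was lower over the night times together, though it stood at 16.3 ± 8.56 CPM at 21 h against 3.66 ± 1.48 CPM at 10.5 h. It was among 3 down and 3 up of 14 flowering genes (the same adjusted over the list alone, camera adjusted p = 0.694). In jasmonate signalling, the repressor genes TIFY11C (-1.14 ± 0.38) and TIFY11E (-1.39 ± 0.36) were lower at night and JAR2 higher (1.16 ± 0.31). Of these, 6 of 16 were down and 1 up (the same adjusted over the list alone, camera adjusted p = 0.394). This list goes with the mature pollen list across libraries (r = 0.57).

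Dusk and dawn also differed in opposite directions within lists. BAM2 was lower at dusk (-2.28 ± 0.45), while AMY3D (3.39 ± 0.81) and GWD1 (0.74 ± 0.20) were higher. Of 6 starch breakdown genes 3 were called (2 up and 1 down, the same adjusted over the list alone, camera adjusted p = 0.965). This list goes with the mature pollen list across libraries as well (r = 0.79). SUS4 was higher at dusk (1.41 ± 0.25), and SUT2 (-1.15 ± 0.18) and the vacuolar invertase INV3 (-2.91 ± 0.75, chosen after its value was seen) were lower. Of 17 sugar genes 1 was up and 3 were down (the same adjusted over the list alone, camera adjusted p = 0.965). NIA1 was lower (-3.33 ± 0.58), and NIR1 (1.39 ± 0.27) and NADH-GOGAT2 (1.42 ± 0.39) higher. Of 9 nitrogen genes 2 were up and 3 down (3 up and 3 down adjusted over the list alone, camera adjusted p = 0.965).

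Each count was set against other splits of the same libraries, the real one included. For changes over time 1 of 80 draws gave as many genes (real 10852, highest other 510). For the rhythm it was 1 of 60 (12201 and 2524) and for night against day 1 of 80 (6792 and 1014). In each case the 1 was the real grouping, and no other draw reached its count. This argues against chance, though so few draws cannot exclude it. Of 35 splits each, 1 gave as many from dawn to 3.5 h (2966, highest other 818), 3.5 to 7 h (2221 and 287), 7 to 10.5 h (1069 and 0), 14 to 17.5 h (354 and 1) and 17.5 to 21 h (2208 and 36). The 0 is from edgeR at the adjusted threshold. A share of 1 in 35 is the smallest that these splits can give, and the intervals share libraries. The counts thus argue against chance without excluding it. Mature pollen means also differed between 14 h (0.58 to 2.89) and 17.5 h (-0.51 to 1.82, log2 CPM). For dusk against dawn 2 of 35 splits gave as many (5694, highest other 6680), from 10.5 h to dusk 2 of 35 (48 and 1692) and from dusk to 14 h 3 of 35 (161 and 1340). Chance cannot be excluded by this count. In these 3 cases the split with the most calls put the 4 libraries with the highest mature pollen means on one side, which points to a structure of the samples. With the mature pollen mean as a covariate, chosen after seeing the data, the real counts were 7195, 106 and 188.

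The first pattern is that pollen genes differed between libraries of one time; the tests against cell division and tapetum genes were chosen after the result was seen. Library depth is argued against by r = 0.13 between the mature pollen mean and the log2 library total, and a single scaling factor per library by r = -0.64 with the cell division mean, since such a factor would move both lists alike. A candidate explanation, as a hypothesis, is that panicle pieces differed in their share of anther tissue, or in its stage. Tapetum genes went with pollen genes (r = 0.88), which does not tell share from stage. Starch breakdown genes went with them too (r = 0.79), so the relation is not particular to anther lists. Among the mature pollen genes EXPB13, named after its values were seen, went against the others. Its pairing with its identifier was not checked by the reference table. The floral organ identity list, which holds genes of the stamen and of other organs, showed no relation past the threshold (r = 0.26). As it mixes organs, it does not decide the question either. Apart from these relations no biological explanation was tested, since no group of the design bears on one.

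The second pattern is that dusk replicate 3 held counts at identifiers whose number does not end in 00, which lie between older gene models; the test against neighbours was chosen after the result was seen. Of 5821 such identifiers with counts at dusk, 1690 were at least 8-fold higher there than in the other dusk libraries. Genomic DNA would place the excess at identifiers whatever their neighbour's level. Of the excess, 12.6% lay at identifiers with a neighbour under 10 CPM, which make up 34.8% of them. The excess was summed in CPM, so ordinary spread between libraries at expressed identifiers enters it. No other library was treated in the same way, so this does not decide on genomic DNA. Reads of the neighbouring gene counted on the other strand may be the source: the excess rose with the neighbour's level (Spearman rho across identifiers 0.39, which are not independent replicates, against at most 0.044 in 1000 shuffles). The strand setting of the counting is not given in the sources used here, which keeps this open.

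The third pattern is the low number of genes called on both sides of dusk; the comparison over dusk was added after seeing the data. Without dusk replicate 3, 21 genes were called from 10.5 h to dusk and 100 from dusk to 14 h. Leaving it out thus raised neither count. Fewer libraries can also lower a count: the first was 13 without dusk replicate 2 and 24 without dusk replicate 4. Whether dusk replicate 3 added spread is therefore not decided by this. A shorter time between samples may be the reason, as each of these intervals is shorter than 3.5 h. From 10.5 to 14 h, a gap like that of other intervals, 1478 genes were called (380 up, 1098 down), against 354 in the lowest other interval. That comparison leaves out the dusk libraries, so it does not tell a short gap from spread among them. Libraries that differ in pollen genes at dusk, where replicate 1 stood apart, remain open as a further reason. Without dusk replicate 1, 244 genes were called from 10.5 h to dusk. From dusk to 14 h the count of 161 rose to at most 207 with any library left out.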
